A study of Homo sapiens with 6 samples.

How the data were processed

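Bulk RNA-seq was available for 6 libraries from HK-2 cells, an immortalised line derived from human proximal tubule epithelium. Per the labels, 3 libraries came from wild-type (WT) cells and 3 from knockout (KO) cells. The series title and the sample labels name FAM134B (current symbol RETREG1) as the disrupted gene, whereas the series design text names TAX1BP1. Both genes were therefore examined in every library, and the groups are called WT and KO throughout. The design text describes the 3 libraries of a group as biological duplicates, and nothing in the labels says whether they came from separate cultures or from 1 edited clone or several. The p-values measure the spread between these libraries, which may be smaller than that between independently derived lines.

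Per the labels' protocols, total RNA was extracted with RNAiso Plus, and the rest of the protocol describes reverse transcription and qPCR. The library kit, the strand setting and the read counter are not given in the sources used here. Per the submitters' processing notes, bcl2fastq 2.17.1.14, FastQC 0.10.1, cutadapt 1.9.1, HISAT2 2.0.1 and Cuffdiff 2.2.1 were used, with genome build GRCh37. The deposited gene table lists estimated counts of reads for 16116 genes under NCBI gene numbers and symbols, and a second deposited table lists them for 79852 RefSeq transcripts. Between 13.0% and 14.0% of the estimated counts in a library were not whole numbers, and all were rounded to whole reads before count tests. Summed transcript counts differed from the gene counts by at most 0.06 reads. The authors also deposited TPM values and FPKM values (fragments scaled to transcript length and library size) per library. These units entered only as alternatives, and RETREG1 and TAX1BP1 levels are given in TPM as well. The authors' group means were not used. Libraries held between 16796964 and 17127468 estimated reads. A gene with 3 reads, taken here as the floor, therefore lies at 0.175 to 0.179 CPM (counts scaled to library size). The floors and the counting interval for SOX6 cover counting error only, whereas the interval for TAX1BP1 uses the standard error derived from the edgeR test.

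Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12702 genes. TMM factors, robust dispersions and the quasi-likelihood test of KO against WT followed, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-scaled CPM, given as mean ± SD over the 3 libraries of a group. Log2 fold changes (KO over WT) carry a standard error (SE). It was derived as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. The transcript table was tested the same way, on 44030 transcripts. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Of 29 lists, the 26 with at least 5 tested members entered the test and its adjustment. Camera with an estimated correlation and fry, both also in limma, served as alternatives.

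The comparison, the gene lists, the tests and most alternatives were fixed before the data were examined, as was the rule for naming genes. That rule names RETREG1 and TAX1BP1. It adds the 8 highest and 8 lowest fold changes among called genes with at least 5 CPM in the higher group and no overlap between groups. It also adds, by smallest adjusted p, up to 4 called members of each list that passes and up to 2 of every other list. Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

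Genes were also placed in the order of the NCBI gene table for GRCh38, used only for gene order, chromosomes and names. It had an entry for 16063 of the 16116 genes. No coordinates are given, because the files used another build. Median log2 fold changes were taken over windows of 25 neighbouring genes at 8 CPM or more. They were set against the highest and lowest window medians in 1000 shuffles of the genes. This scan was not part of the fixed design.

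The scripts were tested on simulated counts of 12603 genes for KO against WT, with 50 genes changed at each fold and 12403 left unchanged. In the real data 36.8% of genes were called, so these rates come from a setting with far fewer changes. The edgeR step recovered 44% of genes changed 1.2-fold, 90% of those changed 1.5-fold, 100% of those changed 2-fold and 98% of those changed 4-fold, with 14 false calls (7.78% of its calls). On 12613 simulated genes the list test called the raised list and 0 of 20 unchanged lists, and the window scan found 149 of 150 genes of a simulated block. The simulated genes varied independently and the lists were random. The list result therefore says little about false calls for real lists, whose genes can vary together. Replicate libraries were checked for duplicates. Every pair within a group differed by more than sampling noise, with a chi-square per gene of 2.02 to 6.06, so none was treated as a library deposited more than once. This check does not tell separate cultures from repeat preparations of one RNA.

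Alternatives were DESeq2 1.42.0, other scalings, other filters, limma on log2 TPM or FPKM with pseudocounts of 1 or 0.1, a replicate block, each library left out in turn and other list tests. Offsets for GC content and length, and fits without genes of the shifted chromosome regions, were added after seeing the data.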

Results

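The data compare the transcriptomes of WT and KO HK-2 cells, with 3 libraries in each group. HK-2 is an immortalised human proximal tubule line. The KO cells are labelled as deficient in FAM134B, the product of RETREG1, a membrane-shaping receptor that links endoplasmic reticulum (ER) to autophagosomes during ER-phagy. The comparison asks which transcripts differ when this receptor is disrupted. Libraries held 16796964 to 17127468 estimated reads, and between 14635 and 14859 genes had a value above 0. The most abundant gene, EEF1A1, took 1.17% to 1.33% of reads.

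RETREG1 (NCBI gene 54463) was lower in every KO library. Its reads numbered 72, 80 and 73 in the WT libraries and 33, 27 and 28 in the KO libraries. Normalised levels were 4.41 ± 0.227 CPM in WT and 1.75 ± 0.194 CPM in KO (SD, n = 3 each), so the KO cells held 39.6% of the WT level. In the deposited TPM the means were 2.84 ± 0.217 and 1.15 ± 0.163. The log2 fold change was -1.33 (SE 0.18), with an adjusted p of 5.31e-07 in edgeR's quasi-likelihood test. A two-sided exact permutation test of the 6 CPM values gave p = 0.1, the smallest that 3 libraries against 3 allow. On the scale of log2 of FPKM plus 1, which understates changes of low genes, limma gave -0.64. TAX1BP1 (NCBI gene 8887), an autophagy cargo receptor named in the design text, was at 156 ± 6.30 CPM in WT and 151 ± 9.46 CPM in KO. Its log2 fold change was -0.05 (SE 0.054, 95% interval -0.20 to 0.10), with an adjusted p of 0.533 in edgeR.

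**Figure D1:**
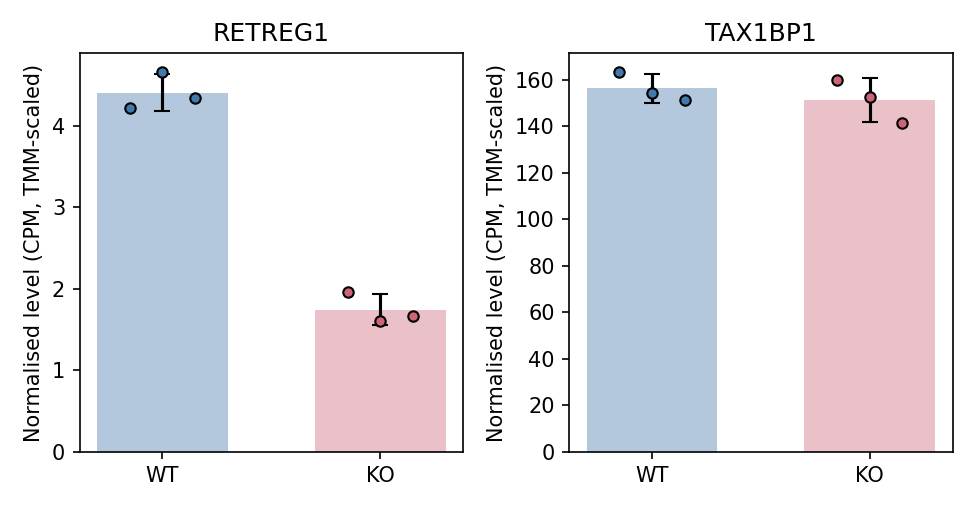
Normalised levels (CPM, TMM-scaled) of RETREG1 and TAX1BP1 in the 3 WT and 3 KO libraries. Points are libraries, bars are group means and error bars are SD. RETREG1 had means of 4.41 and 1.75 CPM with no overlap between groups, whereas the TAX1BP1 values overlapped around means of 156 and 151 CPM.

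The transcript table split the RETREG1 reads over 4 RefSeq models. NM_019000 had 67.6 ± 6.67 estimated reads in WT and 18.5 ± 2.02 in KO, a log2 fold change of -1.85 (SE 0.32) that missed the threshold over all transcripts (adjusted p = 0.0576, edgeR). XM_024446118 had 0 reads in every WT library and 14.64, 6.38 and 11.4 in the KO libraries, which was 36.8% of the RETREG1 reads there. XM_011514053 had 12.3 reads in WT replicate 3 and 0 in the other libraries. NM_001034850 had 3.97 and 5.99 reads in WT replicates 1 and 2 and 0 in the other libraries. These 3 models were too low to be tested, and a split of so few reads between overlapping models is uncertain. Of the 10 listed transcripts of the 2 genes, 6 were tested and 0 passed in edgeR, with 2 at an unadjusted p under 0.05. Over all 44030 transcripts, 503 were higher and 436 lower in KO.

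The KO and WT transcriptomes differed widely. At an adjusted p under 0.05 in edgeR, 2380 genes were higher and 2299 lower in KO, together 36.8% of the 12702 tested. Most of these changes were small. Among the 4679 called genes the median absolute log2 fold change was 0.35, and 3386 changed by less than 1.5-fold. At least 2-fold changes were found for 605 genes, of which 256 were higher and 349 lower. The groups did not overlap for 5876 tested genes (46.3%), against 10% by chance for 3 libraries against 3. Correlations of log2 CPM across genes were at least 0.994 within groups and at most 0.970 between them. The first principal component separated WT from KO and held 78.8% of the variance. The number changed at least 2-fold was 262 with a filter of 5 CPM in 3 libraries and 329 when edgeR tested against 2-fold itself. It was 832 in edgeR with no filter on low counts and between 170 and 618 in 5 limma settings on TPM or FPKM.

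The 8 largest increases under the naming rule were in genes at less than 1 CPM in WT. SOX6, a developmental transcription factor, had 2 reads in the WT libraries together and 811 in the KO libraries, a ratio of 410 (95% counting interval 113 to 3394). NELL2, which encodes a secreted neural glycoprotein, rose from 0.0976 ± 0.0668 to 21.3 ± 1.142 CPM (log2 fold change 7.66, SE 0.22). The fibril-associated collagen gene COL14A1 rose from 0.196 ± 0.135 to 34.3 ± 1.68 CPM. SNAP25, a component of the synaptic vesicle fusion machinery, rose by a log2 fold change of 5.61, and CRACD, a regulator of actin capping, by 5.47. MAN1A1 (a Golgi mannosidase), P2RY1 (an ADP receptor) and SNTB1 (a syntrophin of the dystrophin complex) rose by 4.87, 4.81 and 4.63. Adjusted p-values of these 8 genes in edgeR lay between 6.28e-22 (COL14A1) and 9.50e-13 (P2RY1).

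The largest decrease among the named genes was in STRA6, the cell-surface receptor for retinol-binding protein, which fell from 24.9 ± 0.938 to 0.139 ± 0.0346 CPM (log2 fold change -7.41, SE 0.19). CCND2, encoding cyclin D2, fell from 22.7 ± 1.88 to 0.456 ± 0.150 CPM. ST3GAL5, which makes the ganglioside GM3, had a log2 fold change of -4.42, and the beta-tubulin gene TUBB4A one of -4.29. IL20RB, a receptor subunit for interleukins of the IL-20 family, fell from 58.2 ± 3.91 to 3.65 ± 0.451 CPM. PADI2 (a peptidylarginine deiminase) fell by 3.66 on the log2 scale. The transcription factor gene NFIB had a log2 fold change of -3.50. Adjusted p-values of these 7 genes in edgeR lay between 6.28e-22 (IL20RB) and 1.19e-15 (ST3GAL5).

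**Figure D2:**
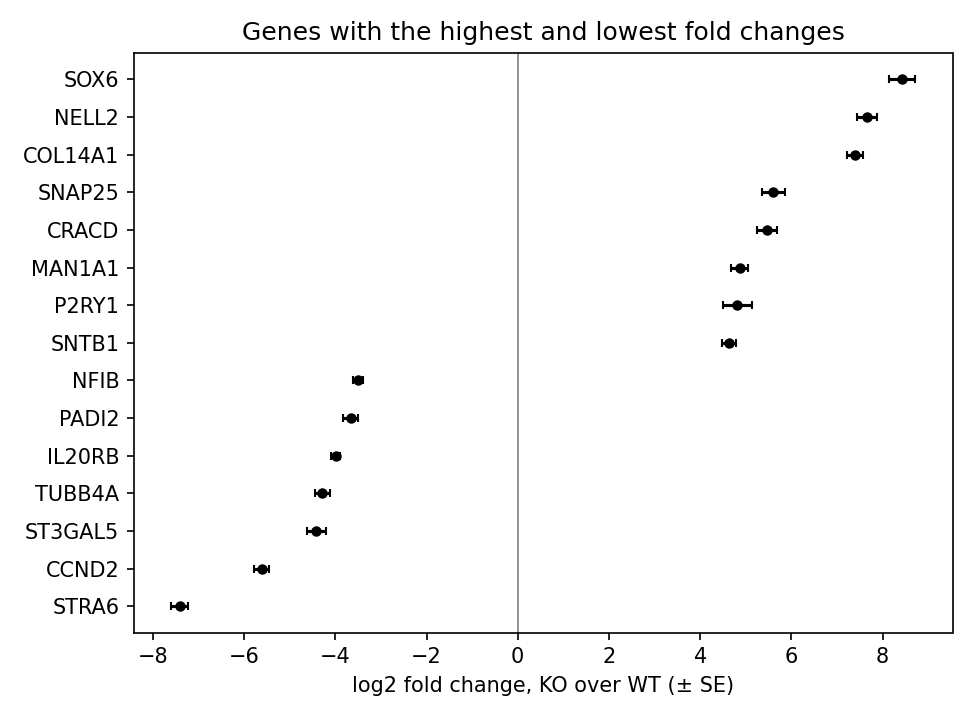
Log2 fold changes (KO over WT) of the 8 highest and 7 of the lowest named genes, with SE derived from the edgeR test as error bars. Values ran from -7.41 for STRA6 to 8.43 for SOX6, whose fitted value rests on 2 WT reads.

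Of 26 gene lists tested with camera, 7 passed the threshold, 4 higher and 3 lower in KO. With an estimated correlation in place of the preset one, the ATF4 and interferon lists passed and the other 5 did not. Fry, which tests whether a list's genes move one way on balance without comparing them with other genes, passed 14.

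Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, rose together. Of 40 tested, 28 rose and 4 fell (31 and 4 adjusted over the list alone), with a median log2 fold change of 0.27 (camera adjusted p = 9.57e-07; adjusted p = 0.0427 with an estimated correlation). TRIB3, a pseudokinase that restrains this pathway, rose from 47.6 ± 3.98 to 134 ± 5.40 CPM. The stress cytokine gene GDF15 rose from 114 ± 6.51 to 289 ± 21.98 CPM, and DDIT3, which encodes CHOP itself, rose 2.02-fold. ALDH1L2, a mitochondrial folate enzyme, went against the list and fell from 7.96 ± 0.506 to 0.952 ± 0.104 CPM. ATF4 itself, named after its value was seen, had a log2 fold change of 0.07 (SE 0.051, adjusted p = 0.311 in edgeR).

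Genes of the NRF2 antioxidant response were also higher in KO. Of 22 tested, 15 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 9.57e-07; adjusted p = 0.0827 with an estimated correlation). AKR1C3, an aldo-keto reductase with close copies among which reads can be split, rose from 1.16 ± 0.0432 to 12.2 ± 0.874 CPM. UGDH, which makes UDP-glucuronate, rose by a log2 fold change of 0.85. GCLC, the catalytic subunit of glutathione synthesis, rose by 0.56, and PGD of the pentose phosphate pathway by 0.39. UGDH and GCLC lie in chromosome regions where most genes were higher, as given below, and PGD lies on chromosome 1.

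Interferon-stimulated genes were lower. Of 34 tested, 3 rose and 19 fell (3 and 21 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 7.11e-07; adjusted p = 0.0427 with an estimated correlation). OASL, of the oligoadenylate synthetase family, fell from 12.8 ± 1.18 to 2.12 ± 0.427 CPM. The antiviral IFIT genes fell alike, with log2 fold changes of -1.60 for IFIT1, -1.37 for IFIT2 and -1.34 for IFIT3.

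The NF-kB target list passed on the higher side, although 2 chemokine genes in it fell steeply. Of 25 tested, 13 rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.00549; adjusted p = 0.340 with an estimated correlation). IL6 rose from 15.3 ± 0.993 to 76.3 ± 3.26 CPM, and TNF, in one of the chromosome regions given below, from 4.78 ± 0.129 to 14.2 ± 0.690 CPM. CCL2, which attracts monocytes, fell from 18.7 ± 0.793 to 2.68 ± 0.670 CPM. The chemokine gene CCL20 fell from 5.90 ± 0.334 to 0.893 ± 0.310 CPM.

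The list of epithelial-mesenchymal transition and TGF-beta response genes passed on the lower side. Of 29 tested, 2 rose and 14 fell (3 and 15 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.00351; adjusted p = 0.113 with an estimated correlation). The integrin gene ITGB6 fell from 56.5 ± 2.23 to 28.5 ± 0.910 CPM, and CDH2, encoding N-cadherin, from 146 ± 7.12 to 94.5 ± 2.40 CPM. The actin-binding gene TAGLN and the TGF-beta-induced PMEPA1 fell by 0.50 and 0.49 on the log2 scale.

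The list of ER chaperone and ER-associated degradation genes passed on the lower side. Of 40 tested, 2 rose, 17 fell and 21 were not called, with the same numbers adjusted over the list alone, and the median was -0.12 (camera adjusted p = 0.0347; adjusted p = 0.340 with an estimated correlation). HSPA5, the ER chaperone BiP, fell from 682 ± 26.1 to 556 ± 12.6 CPM. MANF, DERL1 and the ER stress transducer gene CREB3L2 had log2 fold changes of -0.34, -0.26 and -0.38. The list missed the threshold without WT replicate 1, KO replicate 2 or KO replicate 3 (adjusted p = 0.0740, 0.0635 and 0.0680 in camera). It also missed it without the genes of the 2 shifted chromosome regions (adjusted p = 0.0596), although 0 of its 40 members lie in them. Without those genes and all of chromosomes 1 and 6 the median was -0.11 over 37 members (adjusted p = 0.0576).

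The glycolysis and hypoxia list passed narrowly, on the higher side. Of 30 tested, 13 rose, 4 fell and 13 were not called (14 higher and 5 lower adjusted over the list alone), with a median of 0.15 and a mean of 0.05 (camera adjusted p = 0.0484; adjusted p = 0.531 with an estimated correlation). The glucose transporter SLC2A1 rose from 152 ± 7.08 to 226 ± 8.30 CPM, whereas the transporter SLC2A3 fell by 1.62 on the log2 scale. VEGFA, in a shifted region of chromosome 6, and the phosphofructokinase gene PFKL rose by 0.58 and 0.49 on the log2 scale. The list missed the threshold without WT replicate 1, WT replicate 2, KO replicate 2 or KO replicate 3 (adjusted p = 0.0740, 0.0834, 0.0730 and 0.0933 in camera), and with upper-quartile scaling (adjusted p = 0.05003).

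**Figure D3:**
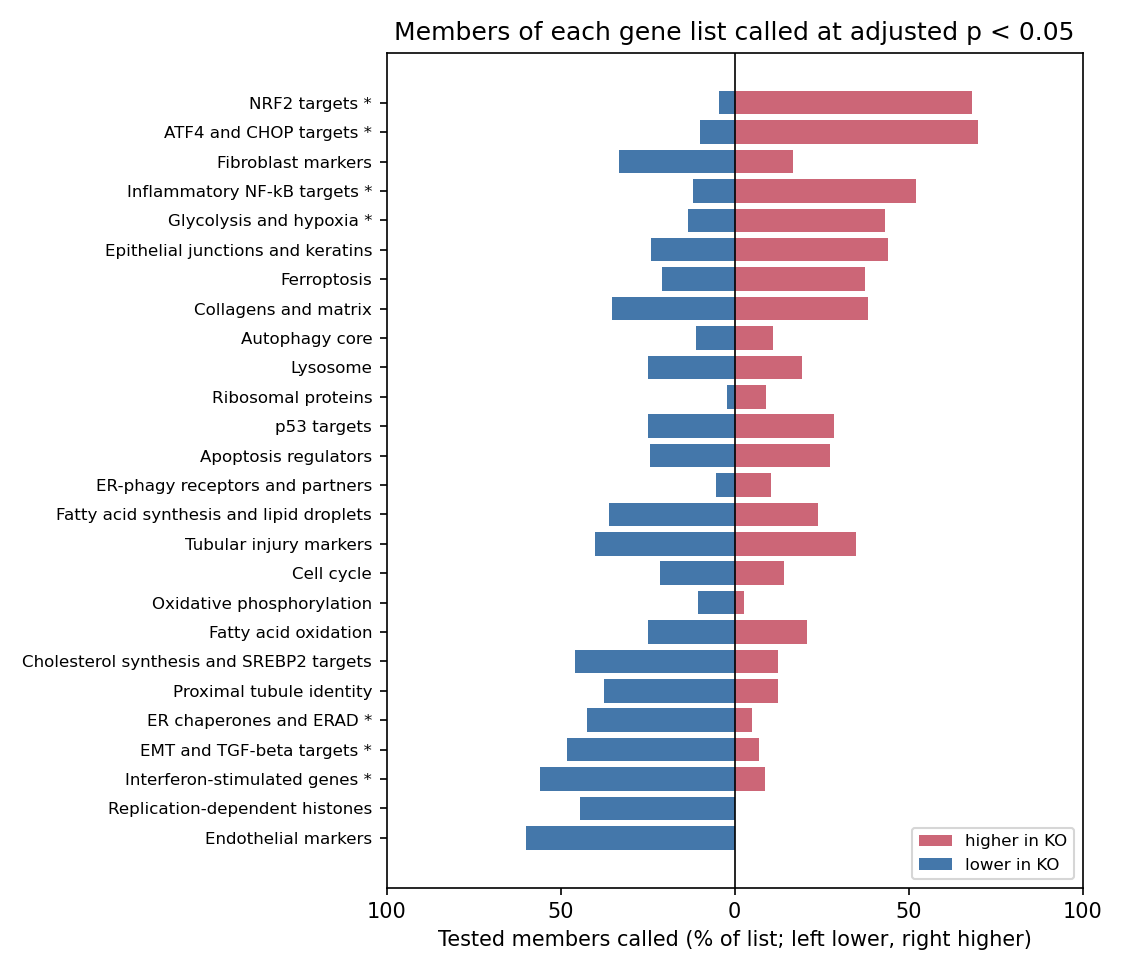
Share of each list's tested members called higher (right) or lower (left) in KO by edgeR, in percent, for the 26 lists tested, ordered by median log2 fold change. An asterisk marks the 7 lists past the threshold in camera, among them ATF4 and CHOP targets (28 of 40 rose) and interferon-stimulated genes (19 of 34 fell).

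The machinery closest to RETREG1 did not pass as a list. Among the other ER-phagy receptors and partners, 2 rose and 1 fell of 19 tested (camera adjusted p = 0.922). RTN3, itself an ER-phagy receptor, rose from 182 ± 5.92 to 217 ± 8.62 CPM, and LNPK, a protein of ER tubule junctions, from 39.6 ± 2.26 to 48.8 ± 4.24 CPM. Of 36 core autophagy genes 4 rose and 4 fell (adjusted p = 0.930). SQSTM1, the cargo receptor p62, rose from 1175 ± 23.0 to 1916 ± 48.7 CPM, and PIK3C3, the autophagy lipid kinase, fell from 68.8 ± 4.30 to 50.8 ± 3.31 CPM. Of 36 lysosomal genes 7 rose and 9 fell (adjusted p = 0.814), with the protease gene CTSL at 0.332 and GAA, the acid glucosidase, at 0.490 of the WT level.

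Lipid and energy lists did not pass either. Cholesterol synthesis genes had 3 higher and 11 lower of 24 (camera adjusted p = 0.188). The sterol reductase gene TM7SF2 rose by 0.74 on the log2 scale. Fatty acid synthesis and lipid droplet genes had 6 higher and 9 lower of 25 (adjusted p = 0.814), with rises in the elongase ELOVL6 from 1.06 ± 0.321 to 7.61 ± 0.495 CPM and in ACSL1, an acyl-CoA synthetase, of 1.74-fold. Fatty acid oxidation genes had 5 higher and 6 lower of 24 (adjusted p = 0.814), and ECI1 and ACADM rose by 0.31 and 0.30. Of 38 oxidative phosphorylation genes 1 rose and 4 fell, among them NDUFV2 (adjusted p = 0.542).

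Tissue identity and injury lists were mixed. Proximal tubule genes had 2 higher and 6 lower of 16 (camera adjusted p = 0.485). The bicarbonate cotransporter gene SLC4A4 fell from 49.5 ± 2.15 to 19.5 ± 1.73 CPM, and PAX8, a renal lineage transcription factor, rose from 458 ± 25.4 to 561 ± 39.5 CPM. Epithelial junction and keratin genes had 11 higher and 6 lower of 25 (adjusted p = 0.542). KRT7 fell from 280 ± 7.20 to 144 ± 9.10 CPM, and the epithelial splicing regulator ESRP1 rose from 0.352 ± 0.0987 to 4.64 ± 0.582 CPM. Tubular injury markers had 7 higher and 8 lower of 20 (adjusted p = 0.542), and CCL2, given above, was among those that fell. CDKN1A, the cell cycle inhibitor p21, rose from 20.4 ± 2.22 to 66.9 ± 3.80 CPM and lies in the shifted region of chromosome 6. Collagen and matrix genes had 13 higher and 12 lower of 34 (adjusted p = 0.603). TGFBI fell from 622 ± 31.9 to 207 ± 6.26 CPM, and the fibrillin gene FBN2 rose from 62.6 ± 1.57 to 132 ± 2.22 CPM. Of 6 fibroblast markers 1 rose (COL14A1) and 2 fell, among them RGS5 (adjusted p = 0.814). Of 5 endothelial markers 3 fell, among them ENG and ESAM with log2 fold changes of -0.51 and -0.55 (adjusted p = 0.0705).

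Growth and survival lists did not pass. Cell cycle genes had 6 higher and 9 lower of 42 (camera adjusted p = 0.814), with CCNB1, encoding cyclin B1, at a log2 fold change of -0.28. MCM3, of the replicative helicase, rose from 419 ± 5.60 to 793 ± 31.7 CPM and lies in the shifted region of chromosome 6. The p53 targets had 8 higher and 7 lower of 28 (adjusted p = 0.814), and BTG2, an antiproliferative gene, fell from 3.92 ± 0.897 to 0.535 ± 0.0598 CPM. Apoptosis regulators had 9 higher and 8 lower of 33 (adjusted p = 0.814), with BCL2 at 0.677 of the WT level and BIRC3 at 1.41. Ferroptosis genes had 9 higher and 5 lower of 24 (adjusted p = 0.257), with POR and SAT1 higher by 0.68 and 0.73 on the log2 scale. Ribosomal protein genes had 4 higher and 1 lower of 45 (adjusted p = 0.576). RPL5 rose by 0.25, and RPS18, which has many pseudogenes and lies in the shifted region of chromosome 6, by 0.58. Histone genes had 0 higher and 4 lower of 9 (adjusted p = 0.143), among them H2BC12 with a log2 fold change of -0.37. The counts of the lists that did not pass differed by at most 2 genes in either direction when adjusted over the list alone. The distal nephron list had 3 tested members, of which CLDN16 rose by 0.59 on the log2 scale, and the leukocyte list had 1, so neither entered the list test. The table held 0 mitochondrially encoded genes. In 6 lists that did not pass (epithelial, lysosome, fatty acid synthesis, ER-phagy, p53 and apoptosis), the median, the mean and camera's direction did not share one sign.

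Genes on the short arms of chromosomes 4 and 6 were higher in KO almost throughout. Of 389 windows of neighbouring genes, 16 had a median log2 fold change above the highest of 1000 shuffles (0.24) and 0 had one below the lowest (-0.22). The 16 windows formed 2 runs. On chromosome 4 the run went from ZNF595 to EXOC1 in 5 windows, the last of which reaches into the long arm, with a median of 0.53 and 93.6% of 125 genes above 0. On chromosome 6 it went from DUSP22 to ZNF451 in 11 windows, with a median of 0.55 and 96% of 275 genes above 0. Each KO library showed the shift, with medians against the WT mean of 0.53, 0.51 and 0.50 on chromosome 4 and 0.50, 0.55 and 0.56 on chromosome 6. The 2 runs held 3.98% of tested genes and 399 of the 2380 genes called higher, or 16.8%. Genes of chromosome 1 were higher by a smaller amount along its length, with a median of 0.12 over 1039 genes, against a highest chromosome median of 0.08 in shuffles. SLC2A1, PGD, ACADM and RPL5, named above as higher, lie on it. Outside the runs and chromosomes 1 and 6 the median was -0.02 over 8394 genes.

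**Figure D4:**
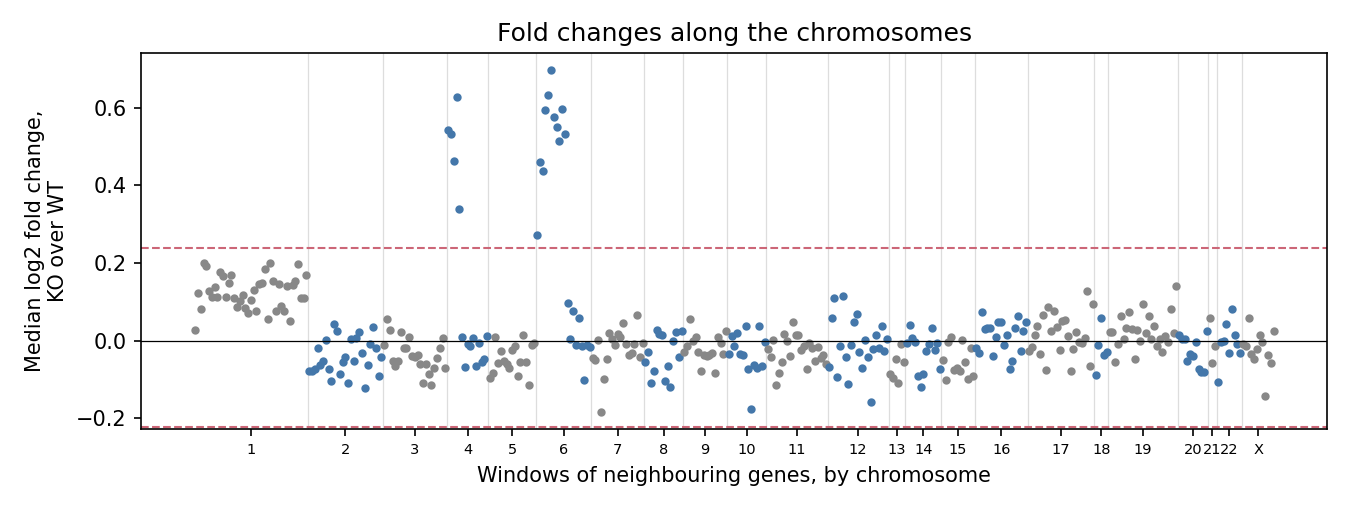
Median log2 fold change (KO over WT) of windows of at least 25 neighbouring genes, ordered along each chromosome of the GRCh38 gene table. Each point is a window and dashed lines are the highest (0.24) and lowest (-0.22) window medians in 1000 shuffles. The 5 windows of chromosome 4 and 11 of chromosome 6 above the upper line lie side by side.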

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

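The GC and length offsets and the fits without genes of the shifted chromosome regions were chosen after seeing the data, and the other alternatives were planned. RETREG1 was lower and past the threshold in all 20 alternatives that tested it, with log2 fold changes of -1.43 to -0.64 and adjusted p-values of 2.26e-11 to 0.000301. It lay below a filter of 5 CPM in 3 libraries, and the smallest change came from limma on log2 of FPKM plus 1, where the pseudocount shrinks low genes. TAX1BP1 missed the threshold in all 21, with adjusted p-values of 0.198 to 0.998. DESeq2 called 3765 genes, of which 3658 were also called by edgeR in the same direction. Leaving out 1 library gave 1964 to 2445 genes higher and 1837 to 2327 lower. The number changed at least 2-fold, 605 in the report, was 262 with at least 5 CPM in 3 libraries, where fewer genes were tested, and 329 in glmTreat against 2-fold, which asks for more evidence. In limma it was 254 on log2 of TPM plus 1, 170 on log2 of FPKM plus 1, 267 on log2 of FPKM plus 0.1 and 191 on log2 of FPKM plus 1 with no filter, and the cause was not tested. With no filter it was 618 in limma on log2 of FPKM plus 0.1 and 832 in edgeR, both above 605. Of 26 lists, camera with an estimated correlation passed 2 and fry passed 14, against 7 in the report. Fry asks another question. Estimating the correlation in camera also changes the degrees of freedom of its test, so the fall to 2 lists cannot be credited to correlation alone. Leaving out 1 library gave 5 to 7 lists. Of 1633 values for 80 named results, 1630 kept direction and side of the threshold and 0 reversed. The other 3 were LNPK in limma, with adjusted p-values of 0.0534 to 0.0615. These genes were named by their values in the same libraries, so this agreement was largely set in advance. Of all 4679 called genes, 3687 were called again in the same direction without KO replicate 2. In limma on log2 of TPM plus 1, where fewer genes were tested, 3497 were. Whether the replicate numbers pair the libraries is not settled. Same-numbered libraries deviated together with correlations across genes of 0.43, 0.02 and 0.37, and WT replicate 2 did not correlate best with KO replicate 2. WT replicate 1 with KO replicate 3 was at -0.41 and WT replicate 3 with KO replicate 1 at -0.38. Each group was centred on its own mean, which makes some values negative where others are positive. These negative values therefore add no support of their own, and variation shared by number is not excluded. A replicate block called 3013 genes higher and 2934 lower, with 606 changed at least 2-fold, 7 lists and 0 target transcripts past the threshold. Depth limits RETREG1 itself, which had 27 to 33 reads per KO library, and the genes near the floor of 3 reads.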

Other observations

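The gene families, the genes named here, the window scan and the tests of explanations in this part were chosen only after the results were seen, and what each test would show was also written down after. Genes of the HOX clusters, which hold positional identity in developing tissues, were mostly lower in KO. Of 27 tested, 16 fell and 3 rose, with a median log2 fold change of -0.50. HOXB2 went from 3.37 to 0.119 CPM, HOXB3 from 7.35 to 2.88 CPM and HOXA3 from 31.9 to 20.6 CPM, and all 3 passed the threshold in edgeR. The genes that rose were neighbours in the HOXD cluster, with log2 fold changes of 0.91 for HOXD9, 0.98 for HOXD10 and 0.93 for HOXD11. Each of 3 other scalings of the counts called 17 lower and 3 higher, and limma on TPM called 12 lower and 3 higher of 23, with a median of -0.29.

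Of 9 tested histone genes, 6 lie in the shifted windows of chromosome 6, and whether they differ from the other genes there was not tested. Of these 6, H2BC12 and H3C4 fell in edgeR, with log2 fold changes of -0.37 and -0.97, and the other 4 were not called, with values from -0.36 to 0.15. Histone genes are near-identical copies among which reads can be split, so single values are uncertain.

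The first pattern weighed is the rise of genes on the short arms of chromosomes 4 and 6. GC content or length bias is argued against, because with offsets for both the median of these genes was 0.54 (quartiles 0.35 and 0.66), still above the 0.24 of the shuffles. A candidate explanation is more copies of these arms in the KO cells than in the WT cells. Genes of low, middle and high expression (133 or 134 each) had medians within 0.0208 of each other, as a dosage change needs. The median of 0.54 is near the 0.58 of 3 copies over 2 and above the 0.42 of 4 copies over 3. Where the short arms end, values went from OCIAD2 (0.43) to DCUN1D4 (0.04) on chromosome 4 and from PRIM2 (0.60) past MTRNR2L9 (-0.91) to PTP4A1 (0.10) on chromosome 6, without a clean edge, since FRYL before the first end was at -0.18 and ERVMER34-1, PHF3 and LMBRD1 after the ends were at 0.35, 0.24 and 0.31. DNA was not measured here, and a ratio of KO to WT does not tell a gain in the KO cells from a loss in the WT cells. A gain that followed the edit and one carried by the founder of the KO cells also cannot be separated with these libraries.

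The second pattern is the set of genes near the floor in one group and expressed in the other. With at least 1 CPM in one group and at most 3 reads in every library of the other there were 39 genes, 26 on in KO and 13 on in WT. KRT19, a keratin, had 3.13 CPM in WT and 0.0397 in KO, ATP2B4, a calcium pump, 4.45 and 0.0397, and CHST9, a sulfotransferase, 0 in WT and 3.53 in KO. The median SD between KO libraries was 1.04 times that between WT libraries, so the KO libraries differed among themselves about as much as the WT libraries. Whether the KO libraries came from several separately derived lines is not decided by this. The labels do not say whether the WT libraries share a line, and these genes were picked for like values in every library of a group. A line that had diverged from the WT cells apart from the targeted gene may account for these genes, and it cannot be told apart from an effect of the knockout, since both differ between the same groups.

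The third pattern is the rise of ATF4 and NRF2 targets with the fall of interferon-stimulated genes. The 3 lists did not need their own members on the shifted arms or on chromosomes 1 and 6. Without those genes all 3 passed in camera, with a highest adjusted p of 2.45e-06. Removed were 6 of 40 ATF4 and CHOP targets, 6 of 22 NRF2 targets and 8 of 34 interferon-stimulated genes. Of these, 0, 2 and 3 lie on the shifted arms, so the removal could decide little about the arms. Camera compares a list with the other genes, so raised genes outside a list can push it lower, and these were removed too. Effects of the shifted genes on genes elsewhere were not tested and stay open. GC content or length bias is argued against by a highest adjusted p of 8.77e-07 with offsets for both. An effect of the edited gene, which the labels and the design text name differently, a stress state of this line and culture conditions stay open, and an estimated correlation took the NRF2 list to an adjusted p of 0.0827. Camera with the preset correlation also passed lists when the libraries were regrouped, although each other split parts the groups 2 against 1: the ATF4 list passed in 7 of 9 other splits, the NRF2 list in 6 and the interferon list in 4, with smallest adjusted p-values of 0.00232, 0.00248 and 0.000446.

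The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes higher, genes lower and genes changed at least 2-fold, 1 of the 10 splits, the real one, gave as many. The real split gave 2380 genes higher, 2299 lower and 605 changed at least 2-fold in edgeR, and the highest of the other splits gave 0 for each. Each other split has WT and KO libraries in both of its groups. The difference between KO and WT then adds to the spread within groups, so few calls were set in advance and say little about chance. Those other splits had 49 to 606 genes at an unadjusted p under 0.05 in edgeR and at most 1 called gene in DESeq2. For gene lists past the threshold, the real split gave 7 and the highest other split 6, so 1 of the 10 again gave as many. Of the other lists past the threshold in the real split, the glycolysis list passed in 3 of the 9 other splits and the ER chaperone, EMT and NF-kB lists in 1 each. Ribosomal proteins passed in 6 (smallest adjusted p 3.54e-15) and oxidative phosphorylation in 4 (smallest adjusted p 1.54e-06) without passing in the real split.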
